A study of Homo sapiens with 4 samples.

How the data were processed

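RNA of 4 sorted fractions of the Huh7 line was measured on Affymetrix Human Gene 1.0 ST arrays, 1 array for each of CD133-positive, CD133-negative, ALDH-positive and ALDH-negative cells. Total RNA was extracted with Trizol and labelled with biotin, per the labels' protocols. The deposited values are log2 expression values from RMA (robust multi-array averaging), per the submitters' processing notes; the log2 scale was read from the range of the values, 0.556 to 13.5. The software, its version and the genome build were not given in the sources used here, and whether values were centred or filtered after RMA is not stated there. RMA forces the arrays towards one distribution, so a shift shared by most genes cannot be seen in these values, and it compresses differences of dim probes.

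The table held 28869 probes. The platform annotation gave 19310 of them exactly 1 gene symbol and 1752 several, and 7807 were not listed there. Of the probes with 1 symbol, 19279 matched a current gene by its gene identifier in a RefSeq table of assembly GRCh38.p14, used for names and RNA class only, and 0 symbols had to be updated. No gene was named from a probe with several symbols. A gene's value was that of its probe with the highest mean over the 4 arrays, which left 18377 genes, 685 of them with more than 1 probe. Coordinates are not printed because the build behind the probes is not known here.

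For each sort the log2 value of the negative fraction was subtracted from that of the positive fraction. A gene counted as above the floor where the brighter array of the sort reached 4.98, the median of all values. Genes were counted at 2-fold, with no test, since 1 array per group gives no spread. Shared genes were set beside the number that independent lists would share. Pearson's r, Spearman's rho and the shares of the summed squares were computed over genes above the floor in at least 1 sort, with intervals from 1000 bootstrap draws over genes. Marker status was tested over both sorts with limma (lmFit and eBayes, Benjamini-Hochberg adjustment) on all 4 arrays with the sort as a block. This design has 1 residual degree of freedom, which is not a test of either sort. Whether arrays came from separate cultures is not stated, so a p-value from this fit measures only the spread between these arrays.

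The 29 gene lists covered liver functions, stem-cell and surface markers, signalling pathways, stress responses, cell division and other cell types. Each list's median difference was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, and was called outside when beyond the middle 95% of them. That position describes these arrays and is not a test across replicates. Over both sorts the lists were tested with camera, with a preset correlation of 0.01 and with an estimated one. The design, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where the text says otherwise. Named were PROM1 and the aldehyde dehydrogenases, the 12 genes with the largest difference in each direction per sort, the 10 genes highest and the 10 lowest in both sorts at 1.5-fold, and per list up to 4 members at 2-fold or else the 2 with the largest difference. Other genes, such as further members that illustrate a list and the genes of the closing part, were chosen after their values were seen.

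Alternatives were another fold threshold (1.5-fold), no floor, a floor at the 75th percentile of all values, the mean over a gene's probes, each probe on its own, centring of each pair, a second quantile normalization, loess with a span of 0.4, other settings of limma and of camera, and leaving out each array in the fit without the block. Exchanged ALDH labels, and values below the floor raised to it, were added after the data were seen. The limma fit was tested on simulated data of 12177 genes, with a spread drawn from the disagreement of both sorts. It called 30 of 100 genes changed 2-fold, 100 of 100 changed 4-fold and 9 of 11977 unchanged genes, and 109 of the unchanged genes reached 2-fold in a single sort. A simulated list raised 2-fold came out at percentile 100, and 6 of 100 unchanged lists fell outside the range, with genes simulated to vary independently. R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9 were used.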

Results

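Huh7, an established human hepatocellular carcinoma line, was sorted by flow cytometry for CD133 (the product of PROM1) in one pair of fractions and for aldehyde dehydrogenase (ALDH) in another. The marker-positive fraction of each sort was set against its marker-negative fraction, a comparison the series frames as cancer stem cells against other tumour cells. RNA of each fraction was measured on 1 array, 4 arrays in all. Each difference below therefore has no replicate check and no p-value, and is the log2 value of the positive fraction minus that of the negative fraction. The median log2 value per array was 4.99 in CD133-positive, 4.92 in CD133-negative, 5.04 in ALDH-positive and 4.98 in ALDH-negative cells. No array was a copy of another: the correlation over all probes ran from 0.982 to 0.989 over the pairs of arrays. The number of arrays limits the precision of every value.

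PROM1 was 12.8-fold higher in the CD133-positive than in the CD133-negative fraction, at log2 levels of 9.0 and 5.32, so the transcript of the sorted protein followed the labels of this sort. The largest differences after it included several genes known from the intestinal epithelium. The mucin MUC13 was 5.77-fold higher in CD133-positive cells, the disaccharidase SI 5.46-fold, the chloride and bicarbonate exchanger SLC26A3 at least 2.83-fold, the liver-intestine cadherin CDH17 4.27-fold and the peptidase DPP4 4.03-fold. Several genes of secreted liver proteins and of liver enzymes were among those with the largest differences the other way. The haemoglobin-binding protein HP was 3.49-fold lower in CD133-positive cells, fetuin AHSG 2.99-fold, antithrombin SERPINC1 2.84-fold, arginase ARG1 2.53-fold and ornithine transcarbamylase OTC at least 1.44-fold. A fold given as at least takes the expression floor of 4.98, the median of all values, in place of a dimmer array that lay below it.

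Of 11591 genes above the expression floor in this sort, 83 were at least 2-fold higher and 19 at least 2-fold lower in CD133-positive cells. With values below the floor raised to it, an alternative added after the data were seen, the counts were 63 and 13. The median difference was -0.04 and the middle 95% of genes lay between -0.54 and 0.60. In the simulation, with a spread drawn from the disagreement of both sorts, 109 of 11977 unchanged genes reached 2-fold in a single sort. The counts at 2-fold are therefore not counts of changed genes. The 12 highest also held the cartilage collagen COL2A1 (2.46), the superoxide-producing oxidase NOX1 (2.43), the amino acid transporter subunit SLC7A7 (2.36), the collagen COL14A1 (2.14), the annexin ANXA3 (2.07) and the glutathione transferase GSTA2 (1.96). The 12 lowest also held the alcohol dehydrogenase ADH6 (-1.29), plasminogen PLG (-1.22), the glutamine transporter SLC38A3 (-1.17), NSRP1 (-1.16), the transcription factor SNAI2 (-1.15), the acute-phase protein ORM1 (-1.11) and the mitochondrial methionyl-tRNA synthetase MARS2 (-1.06). NOX1, SLC7A7, COL14A1, GSTA2, NSRP1 and SNAI2 lay below the floor in the dimmer array, so their differences and ranks are uncertain; set against the floor, GSTA2 (0.62), NSRP1 (-0.78) and SNAI2 (-0.29) were short of 2-fold. GSTA2, HP and ORM1 have close paralogs that can share probe signal, and their values are uncertain for that reason.

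**Figure D1:**
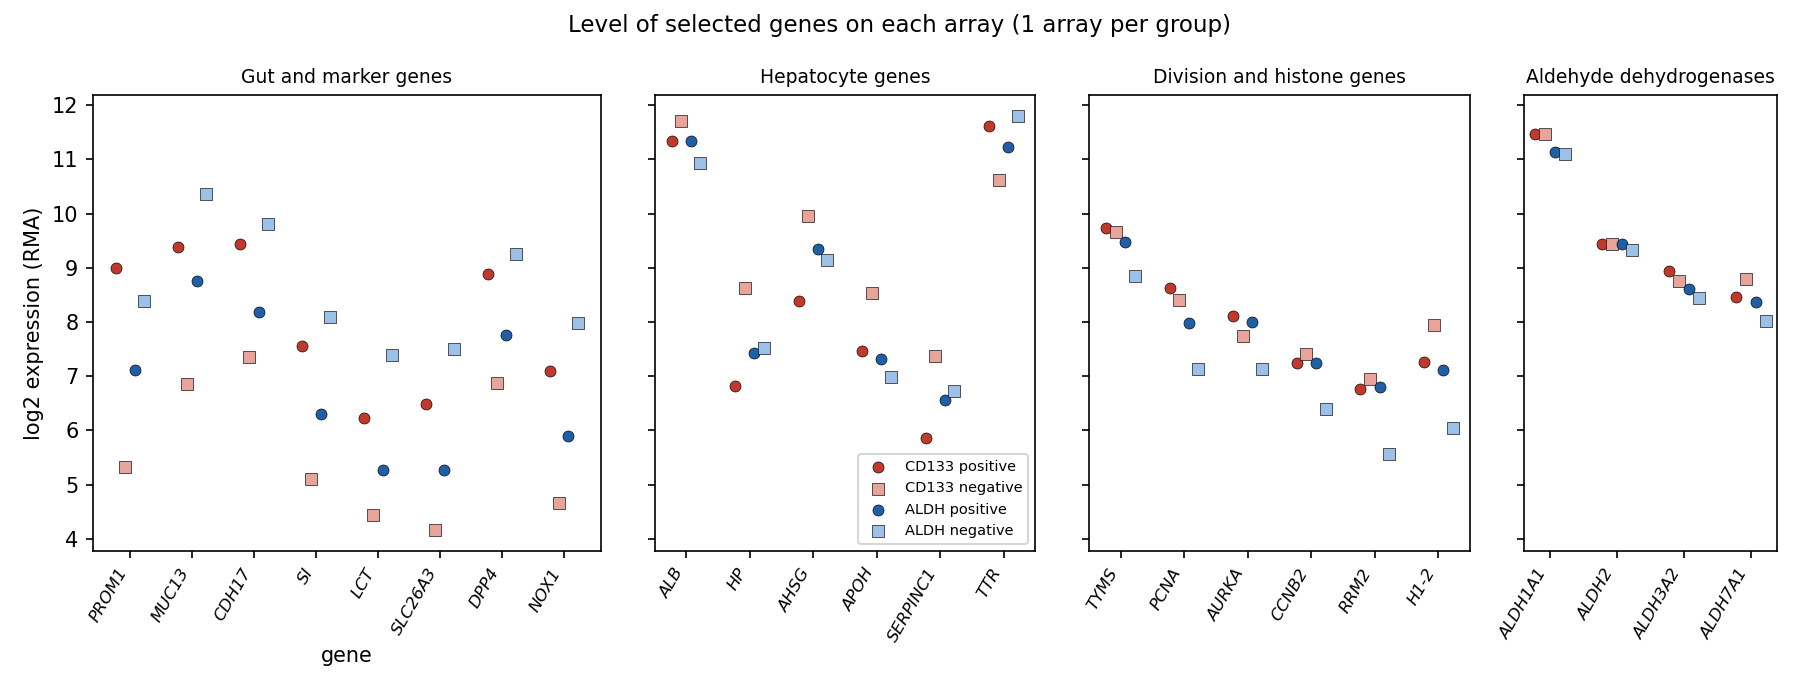
Log2 expression (RMA) of selected genes on each of the 4 arrays, 1 point per array, with circles for marker-positive and squares for marker-negative cells. PROM1 lies at 9.0 in CD133-positive and 5.32 in CD133-negative cells, while ALDH1A1 lies at 11.14 in ALDH-positive and 11.10 in ALDH-negative cells.

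Liver and lipid genes were lower as groups in CD133-positive cells. Of 28 measured genes of hepatocyte products and functions, 21 were lower and 7 higher, with a median of -0.27, below all 10000 random lists matched on expression. HP, AHSG and the apolipoprotein APOH (-1.05) were at least 2-fold lower; APOH was just short of 2-fold after a second quantile normalization (-0.99). ALB, the gene of albumin, differed by -0.38, and TTR, the gene of the thyroid hormone carrier transthyretin, went the other way at 0.99. In the same sort, 23 of 25 measured genes of an intestinal list, written after the data were first seen, were higher in CD133-positive cells, with a median of 0.30 above all random lists. Of 15 genes of fatty acid synthesis and lipid droplets, 13 were lower, with a median of -0.38 that also lay below all random lists. The acyl-CoA synthetases ACSL4 (-0.67) and ACSL1 (-0.60) differed most, and none of the 15 reached 2-fold. All 13 genes of cholesterol synthesis and uptake were lower, with a median of -0.26 at percentile 0.03, led by STARD4 (-0.61) and MVD (-0.50), none of them 2-fold. Of 10 replication-dependent histone genes, 8 were lower, with a median of -0.30 at percentile 0.14 and no member at 2-fold; histone genes are near copies of each other, so single members are uncertain.

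The lists of surface markers used to isolate liver cancer stem cells and of fetal liver and biliary progenitor markers were higher in CD133-positive cells, with medians of 0.16 over 13 genes (percentile 98.96) and 0.11 over 15 genes (percentile 98.4). Both lists hold PROM1, and both lost that position without it, at percentiles 93.05 and 76.25, in a recalculation added after the data were seen. With PROM1 kept, the progenitor list also lost it over its 14 members above the floor (percentile 79.7). Besides PROM1, the epithelial adhesion molecule EPCAM (1.10) in both lists and the biliary keratin KRT19 (1.34) in the progenitor list were at least 2-fold higher; the lower of EPCAM's 2 probes gave 0.77. The fetal liver protein AFP differed by -0.09. Among genes of epithelial-mesenchymal transition, the matrix protein SPARC (1.09) and the intermediate filament VIM (1.03) were at least 2-fold higher. SNAI2 (-1.15) was lower, but short of 2-fold against the floor (-0.29). The list median was 0.08, inside the random range. After loess that list lay just above the range (percentile 97.9), and in the ALDH sort its median was -0.05, inside the range, but -0.24 at percentile 0.97 over its members above the floor.

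In the ALDH sort, the genes of the enzymes that give the sort its name hardly differed. ALDH1A1 differed by 0.04, ALDH2 by 0.10 and ALDH1A3 by 0.45, and none of the 19 measured aldehyde dehydrogenase genes reached 2-fold in either sort. The largest difference among them in the ALDH sort was that of ALDH1L2 at -0.65, and the list median was 0.01. These transcripts therefore do not check the labels of the ALDH sort. PROM1 was 2.42-fold lower in ALDH-positive cells.

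Cell division genes were higher in ALDH-positive than in ALDH-negative cells, and several genes known from the intestinal epithelium were lower. RRM2, a subunit of the ribonucleotide reductase that makes deoxynucleotides, was 2.34-fold higher in ALDH-positive cells, and the histone gene H4C13 2.75-fold. SLC26A3 was 4.72-fold lower, the lactase LCT 4.33-fold, NOX1 4.27-fold, the vitamin B12 receptor CUBN at least 3.02-fold and SI 3.44-fold. Of 11879 genes above the floor, 33 were at least 2-fold higher and 154 at least 2-fold lower (12 and 116 with values below the floor raised to it), with a median difference of -0.01 and the middle 95% of genes between -0.84 and 0.67.

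The 12 highest in ALDH-positive cells also held the kinesin KIF2B (1.90), LAMP5 (1.60), the secreted glycoprotein RELN (1.41), the microRNA gene MIR503 (1.40), lysozyme LYZ (1.33), DUSP29 (1.26), LILRB2 (1.20), HHIPL1 (1.18), DENND1C (1.18) and TPBG (1.16). All of these but RELN and LYZ lay below the floor in ALDH-negative cells, so their differences and ranks are uncertain, and set against the floor only LAMP5 (1.02) and TPBG (1.09) stayed at 2-fold. RELN, at 7.84 in ALDH-positive and 6.42 in ALDH-negative cells, and LYZ, at 7.77 and 6.44, were well above it. The 12 lowest also held LRRC66 (-1.95), GSTA2 (-1.92), the bile acid transporter subunit SLC51A (-1.83), the cytokine IL18 (-1.71), AGR2 (-1.66), the mucin MUC12 (-1.65) and the ubiquitin pseudogene UBBP4 (-1.63). LRRC66, GSTA2, AGR2 and MUC12 lay below the floor in ALDH-positive cells, and LRRC66 (-0.51) was short of 2-fold against it. The 3 probes of MUC12 disagreed, with 1 of them at 0.016, and UBBP4 can share signal with its parent gene.

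Of 28 mitotic and S-phase genes, 24 were higher in ALDH-positive cells, with a median of 0.45 above all 10000 random lists. Besides RRM2 none reached 2-fold; the mitotic kinase AURKA (0.88), the cyclin CCNB2 (0.85) and the replication clamp PCNA (0.84) came next. In this sort 18 of the 25 intestinal genes were lower in ALDH-positive cells, with a median of -0.27 at percentile 0.01. Of 10 replication-dependent histone genes, 9 were higher, with a median of 0.55 above all random lists, and H1-2 (1.09) was at least 2-fold higher. Of 14 ABC drug efflux transporter genes, 13 were lower in ALDH-positive cells, with a median of -0.27 at percentile 1.02. ABCC2 (-1.46), ABCG2 (-1.26) and ABCB1 (-1.07) were at least 2-fold lower. Of 20 genes of the unfolded protein and amino acid stress responses, 16 were lower, with a median of -0.24 at percentile 0.49, and the cystine transporter SLC7A11 (-1.23) alone reached 2-fold. Of 19 genes of xenobiotic metabolism, 13 were lower, with a median of -0.23 at percentile 0.32 and GSTA2 as the only member at 2-fold; over the members above the floor alone the median was at percentile 15.1. The surface marker list had a median of 0.07 but a mean of -0.26, since PROM1, ABCG2 and EPCAM were at least 2-fold lower. EPCAM was so only just, with -0.96 after a second quantile normalization and -0.68 from its other probe. Over its 9 members above the floor the median was -0.28 at percentile 1.63. The progenitor list likewise had a median of 0.04 and a mean of -0.17. In the hepatocyte list, whose median of -0.06 was inside the random range, the urea cycle enzyme CPS1 (-1.12) was at least 2-fold lower, though short of it against the floor (-0.37). In the CD133 sort CPS1 lay below the floor and differed by 0.46.

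**Figure D2:**
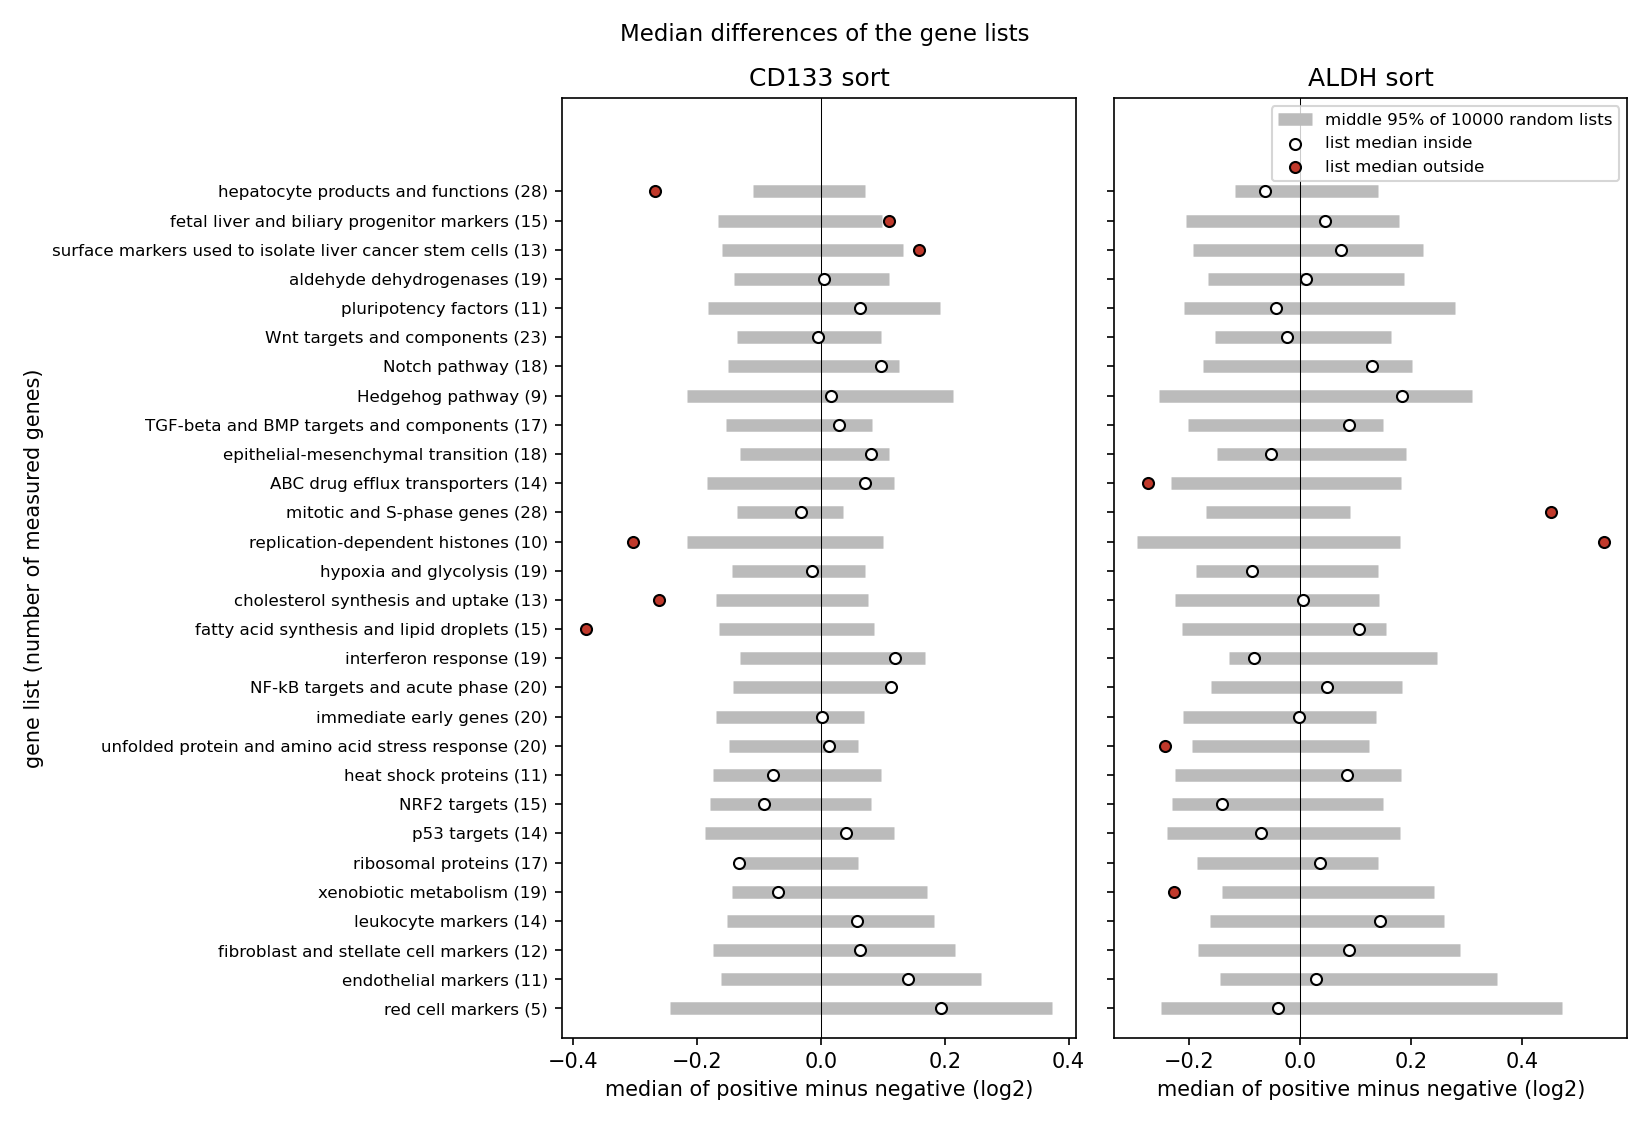
Median log2 difference (positive minus negative) of each of the 29 gene lists in the CD133 sort and the ALDH sort, with grey bars for the middle 95% of 10000 random lists. Filled points lie outside their bar, 6 in the CD133 sort and 5 in the ALDH sort.

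Lists of stem-cell and signalling pathways lay inside the middle 95% of random lists in both sorts, with medians given here for CD133 and then ALDH. They were 0.06 and -0.04 for pluripotency factors, -0.01 and -0.02 for Wnt, 0.10 and 0.13 for Notch, 0.02 and 0.18 for Hedgehog, and 0.03 and 0.09 for TGF-beta and BMP. The Notch list was the exception to this under other settings: in the CD133 sort it lay above the range after loess (percentile 98.5) and over its members above the floor (percentile 98.4). Among pluripotency factors KLF4 differed most, at 0.98 in the CD133 sort and -1.07 in the ALDH sort. Of the 14 genes of that list 11 were measured, without POU5F1, NANOG and BMI1, and 6 were above the floor in at least 1 sort. Its median therefore says nothing about those core factors. Of the 29 lists, 23 lay inside the range in the CD133 sort and 24 in the ALDH sort. If list members varied independently, 1.45 lists per sort would lie outside. Members of a list can vary together, so more lists than that can lie outside by chance. NF-kB targets, with a median of 0.11 at percentile 97.45 in the CD133 sort, lay at the edge of the range, as did ribosomal protein genes with -0.13 at percentile 2.66. Stress and other response lists gave 0.00 and -0.00 for immediate early genes, -0.02 and -0.09 for hypoxia and glycolysis, 0.12 and -0.08 for interferon response (percentile 99.1 in the CD133 sort over the members above the floor), -0.08 and 0.08 for heat shock proteins, -0.09 (with a mean of 0.12) and -0.14 for NRF2 targets, and 0.04 and -0.07 for p53 targets. AKR1B10, an aldo-keto reductase among the NRF2 targets, differed by 1.32 and -1.20.

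Markers of other cell types lay inside the random range in both sorts. Their medians in the CD133 and ALDH sorts were 0.06 and 0.14 for leukocytes, 0.06 and 0.09 for fibroblasts and stellate cells, 0.14 and 0.03 for endothelium, and 0.19 and -0.04 for red cells. Above the floor in at least 1 sort were 6 of 14 leukocyte, 6 of 12 fibroblast and stellate, 3 of 11 endothelial and 0 of 5 red cell markers. Medians over such dim genes say little about these cell types. Over the 6 leukocyte markers above the floor, LYZ among them, the median in the ALDH sort was 0.41 at percentile 99.7. By RNA class, 175 small nucleolar RNA genes had a median of -0.15 in the CD133 sort and -0.15 in the ALDH sort, 633 long non-coding RNA genes had medians of 0.08 and 0.17, 173 microRNA genes 0.05 and 0.13, and 16866 protein-coding genes -0.01 and 0.03.

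The pair of sorts was then compared, to see whether both markers part the cells along the same genes. Many genes with large differences went in opposite directions, most of all those higher in CD133-positive cells. Among 11293 genes above the floor in both sorts, 47 were at least 2-fold higher in CD133-positive and at least 2-fold lower in ALDH-positive cells, where independent lists would share 0.935. PROM1 (3.68 and -1.28), MUC13 (2.53 and -1.60), SI (2.45 and -1.78), NOX1 (2.43 and -2.09), CDH17 (2.10 and -1.62) and LCT (1.79 and -2.11) were among them. The reverse held for 1 gene, the amino acid transporter SLC6A14 (-1.01 and 1.09), named after its values were seen, against 0.0346 for independent lists. None of the 11293 genes was at least 2-fold different in the same direction in both sorts, against 0.163 higher and 0.199 lower for independent lists. The antisense RNA gene THUMPD3-AS1, named after its values were seen, was higher in both (1.65 and 1.04) but lay below the floor in the ALDH sort. It was also below the floor in CD133-negative cells, and its CD133 difference against the floor was 0.20. With values below the floor raised to it, 35 genes and 0 genes were opposite at 2-fold, and none agreed. The direction rests on the ALDH labels, which the transcripts did not check: with these exchanged, an alternative added after the data were seen, the 47 genes would be higher in both positive fractions and SLC6A14 lower in both.

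At 1.5-fold, 13 genes were higher in both positive fractions and 16 lower in both, against 10.5 and 11.5 for independent lists, while 139 were higher in CD133-positive and lower in ALDH-positive cells, against 18.9. The genes lower in both included the muscarinic receptor CHRM3 (-1.01 and -0.88), the centrosomal protein CEP170 (-0.79 and -1.26), ANKRD36B (-0.90 and -0.96) and the mitochondrial pseudogene MTND2P28 (-0.70 and -0.94), whose probe can read the mitochondrial transcript. Those higher in both included the histone H2AC14 (0.63 and 1.13), the xylosyltransferase XYLT1 (0.60 and 0.88) and the granzyme GZMH (0.68 and 0.75). CHRM3, CEP170, ANKRD36B, XYLT1 and GZMH lay below the floor in the dimmer array of both sorts, so their differences are uncertain. Set against the floor, CHRM3 was only 1.18-fold lower in the CD133 sort, and CEP170 was 1.55-fold lower in the ALDH sort.

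**Figure D3:**
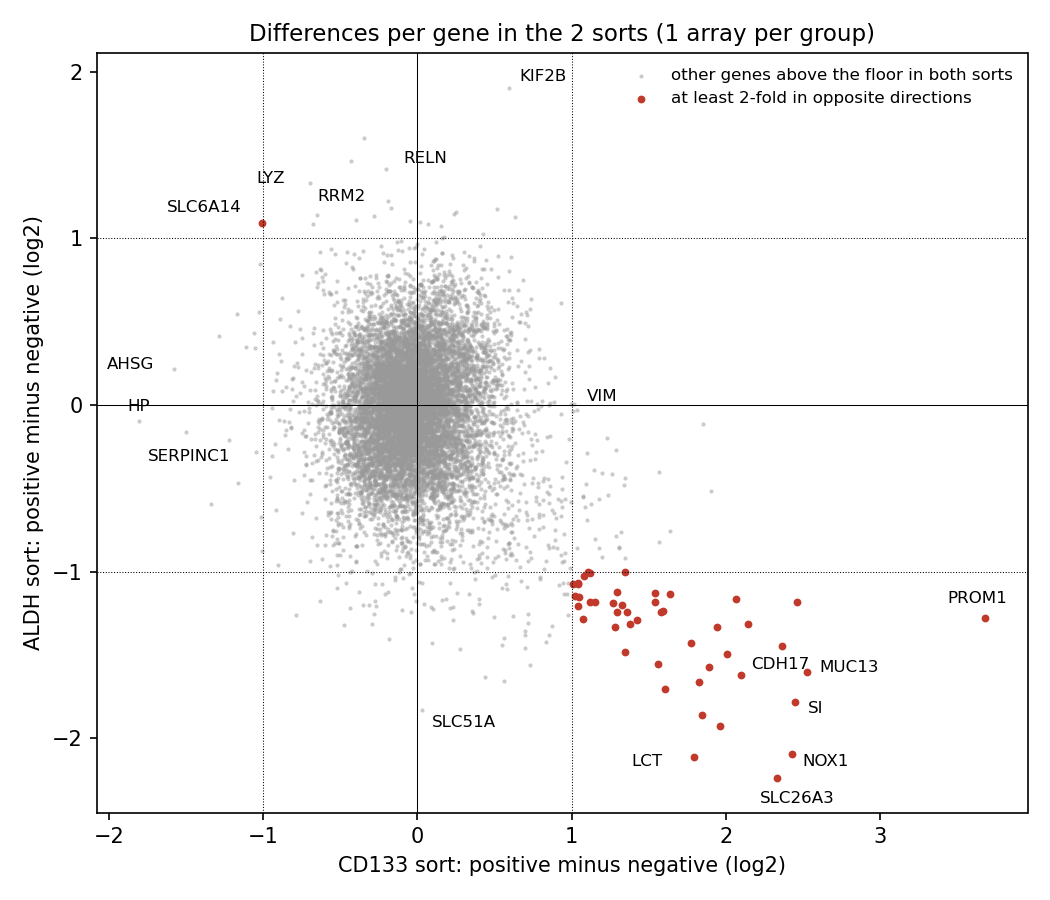
Log2 difference (positive minus negative) of each gene above the floor in both sorts, with the CD133 sort on the horizontal and the ALDH sort on the vertical axis, 1 point per gene. Red points mark the genes at least 2-fold different in opposite directions, 47 at the lower right and 1 at the upper left.

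The 82 genes at least 2-fold higher in CD133-positive cells, PROM1 left out, had a median of -1.07 in the ALDH sort, and 80 of them were lower there. The 153 genes at least 2-fold lower in ALDH-positive cells, again without PROM1, had a median of 0.56 in the CD133 sort, and 118 were higher there. Both medians lay outside all 10000 random lists. The 19 genes at least 2-fold lower in CD133-positive cells had a median of 0.34 in the ALDH sort at percentile 99.97, with 11 higher and 8 lower, among them ARG1 (-0.59) and HP (-0.10). The 33 genes at least 2-fold higher in ALDH-positive cells showed no such turn: their median in the CD133 sort was -0.05 at percentile 14.9, inside the random range, and KIF2B, the highest of them, was also higher in CD133-positive cells (0.59). Over 12177 genes the differences of the 2 sorts had a Pearson r of -0.11 (95% bootstrap interval over genes -0.14 to -0.08) and a Spearman rho of 0.026 (0.0085 to 0.044); genes are not independent replicates. The sign of rho depended on the floor: at the 75th percentile of all values rho was -0.12 and r -0.29, and with no floor they were 0.084 and -0.022. Of the summed squares of the 4 arrays, 25.4% fell to marker status, 43.2% to the sort and 31.4% to their interaction. With 1 array per group no share is left for noise, and equal noise alone would split the squares about equally among these parts. The share of marker status therefore does not show that the marker explains it. With the ALDH labels exchanged, marker status would hold 31.4% and the interaction 25.4%, and r and rho would change sign.

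Marker-positive against marker-negative cells were also tested over both sorts together, with the sort as a block and 1 residual degree of freedom. At a Benjamini-Hochberg adjusted p under 0.05, limma called 0 of 12177 genes, and the smallest adjusted p was 0.889. At an unadjusted p under 0.05 it called 592 genes, where chance gives 609, and without the block it called 0 after adjustment and 305 before it. Adjusted over the list alone, 0 members of the fixed lists passed. In camera, limma's set test, 5 lists passed with a preset correlation between genes of 0.01 and 0 with an estimated correlation. The estimated setting rests on the 1 residual degree of freedom, so hardly any list could pass it. For xenobiotic metabolism camera's p went from 0.0019 to 0.18, although its estimated correlation was -0.05. Failing that setting therefore does not show that correlated genes made the preset calls, nor does it make those calls firmer. With the preset value, mitotic and S-phase genes were higher in marker-positive cells (adjusted p = 0.0065), and hepatocyte (adjusted p = 0.0119), xenobiotic metabolism (adjusted p = 0.0185), cholesterol (adjusted p = 0.0397) and fatty acid genes (adjusted p = 0.0477) were lower; with an estimated correlation each of these had an adjusted p = 0.925. The sorts did not contribute alike: the median was -0.03 in the CD133 sort for mitotic and S-phase genes, and 0.0046 and 0.11 in the ALDH sort for cholesterol and fatty acid genes. With the ALDH labels exchanged, limma called 30 genes, with SLC26A3 and NOX1 first (adjusted p = 0.0144 for each), and camera called 4 lists with the preset value and 0 with an estimated correlation. These calls restate the opposite pattern and do not show which labels are right. The residual of this fit is the disagreement between both sorts, which holds real differences between the markers as well as noise.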

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

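The tests of a large share of foreign cells, of exchanged labels, of a single PROM1-bearing population and of the spread of the liver genes were chosen after the results were seen, and the intestinal list was prompted by the opposite pattern, though written before its own values were seen. The difference between the sorts was not tested for any gene below, since each fraction has 1 array.

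The difference in the CD133 sort and that in the ALDH sort had opposite signs and were each at least 2-fold for 47 genes in one direction and for 1 gene, SLC6A14, in the other. The CD133 difference minus the ALDH difference was 4.96 for PROM1, 4.57 for SLC26A3, 4.52 for NOX1, 4.23 for SI and 4.13 for MUC13. It was 3.91 for LCT, 3.89 for GSTA2, 3.81 for SLC7A7, 3.72 for CDH17, 3.71 for CUBN, 3.64 for COL2A1 and 3.50 for DPP4. It was 3.48 for AGR2, 3.46 for COL14A1, 3.31 for IL18, 3.23 for ANXA3, 2.53 for AKR1B10, 2.11 for EPCAM and 2.08 for ABCB1. The other probe of EPCAM was short of 2-fold in both sorts (0.77 in the CD133 sort and -0.68 in the ALDH sort). SLC26A3, NOX1, LCT, GSTA2, SLC7A7, CUBN, AGR2 and COL14A1 lay below the floor in the dimmer array of at least 1 sort. Their values and their order are therefore uncertain. Set against the floor, GSTA2 differed by 0.62 in the CD133 sort and -1.22 in the ALDH sort. CUBN likewise gave 0.76 and -1.59, and AGR2 0.69 and -1.44. The median of the replication-dependent histone list in the CD133 sort minus that in the ALDH sort was -0.85. Among probes without exactly 1 gene symbol, which no comparison used, 9 were at least 2-fold different in opposite directions.

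Several explanations were weighed for the opposite pattern of the 47 genes, a mixed set with gut genes such as SI and LCT and others such as COL2A1 and IL18. A large admixture of foreign cells in ALDH-negative cells would lower liver genes there. The hepatocyte list would then lie above the random range in the ALDH sort. That was not seen: it lay at percentile 11.97, inside the range, with 11 genes higher and 17 lower in ALDH-positive cells. The list thus gave no sign of a large admixture. A median inside the range over members going both ways does not exclude one, so it stays open. Exchanged ALDH labels stay open, because the aldehyde dehydrogenase list had a median of 0.00997 and so decides nothing; with the labels exchanged, the 47 genes would be higher in both positive fractions. The intestinal list had a median of -0.2745 in the ALDH sort (-0.24 at percentile 0.05 without TSPAN8 and GUCY2C, which are among the 47), which a small admixed intestinal line and gut genes of Huh7 itself would both give, so it does not separate them. A PROM1-bearing subpopulation in another share in each fraction stays open. The median of -1.072 in the ALDH sort of genes higher in CD133-positive cells restates the pattern. PROM1 was lower in ALDH-negative than in CD133-positive cells (-0.61), while the 47 genes had a median of 0.46. That comparison crosses the sorts with 1 array each, and the sort held 43.2% of the summed squares. A difference between the sorts could give it too, so it decides nothing.

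Cell division genes were higher in ALDH-positive than in ALDH-negative cells. An intensity-dependent trend between the arrays is unlikely as the whole cause, since the list median was 0.4913 after loess; that value lies above the middle 95% of random lists. The ALDH-positive array did not stand apart upwards from the CD133 arrays. Against their mean the list's median was -0.09858 at percentile 81.8, inside the random range. Against the same mean, ALDH-negative cells had -0.50, with 27 of 28 genes lower. That comparison crosses the sorts with 1 array each. A difference between the sorts could shift both values, so they do not place the difference in either ALDH fraction. Faster division in the ALDH-positive fraction, slower division in the ALDH-negative fraction and a difference in handling of either array all stay open, as untested.

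Liver genes were lower in CD133-positive than in CD133-negative cells. After loess the hepatocyte list still had a median of -0.2523, which argues against an intensity-dependent trend. Dilution by cells that lack liver transcripts could not be decided from signal level, itself a poor measure of abundance between probes, as an exact two-sided permutation test of the 7 brightest genes against the other 13 gave p = 0.509. Dilution as the whole cause would lower all 20 hepatocyte genes above the floor alike. Their differences, from -1.80 to 0.99 for TTR, had an SD of 0.63 at percentile 99.19 of matched random lists. Without TTR the SD lay at percentile 97.41, just inside the range. The wider spread thus rests on 1 gene and does not decide the question. Dilution, whole or partial, for which 23 of 25 intestinal genes higher in the same comparison could speak, stays open. So does a lower liver programme in CD133-positive cells.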

How the results depend on the processing

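The correlation without the genes of opposite direction, the lists without PROM1 and the intestinal list without its opposite genes were chosen after the results were seen. No paired analysis was possible because each group has 1 array and the labels carry no replicate numbers to pair; the block in limma was the sort. At 1.5-fold the counts were 318 higher and 219 lower in the CD133 sort, 493 and 784 in the ALDH sort, 13 higher in both, 16 lower in both, and 139 and 18 in opposite directions. With the floor at the 75th percentile they were 50 and 10, 8 and 94, and 28 and 0 in opposite directions; r was -0.29, rho turned to -0.12, and the shares of marker status, sort and interaction were 19.7%, 47.6% and 32.7%. Both thresholds change these counts by their construction. With no floor, 30 genes were lower in the CD133 sort, 79 higher in the ALDH sort, 4 higher in both and 3 lower in CD133-positive but higher in ALDH-positive cells; r was -0.022, rho 0.084, and the shares of marker status and sort 29.2% and 40.4%. The reverse-opposite count (SLC6A14) was 0 after centring and 0 after a second quantile normalization, which also gave rho 0.0049 and shares of 40.9% for sort and 33.2% for interaction. Loess gave rho 0.0057 and 24.6% for marker status. Without the opposite genes r was -0.036. The cause was not tested for the normalizations. In camera 0 of 5 lists passed with an estimated correlation, a setting that hardly any list could pass with 1 residual degree of freedom. Leaving out 1 array in the limma fit without the block, with the lone array assumed to vary like the others, gave 0 to 80 genes: 80 without CD133-negative, 38 without ALDH-negative and 0 without either positive array. All other limma settings called 0 genes. The probe of MUC12 with the highest difference gave 0.016 in the ALDH sort, so its sign turned; the cause was not tested. Of 548 single-gene values tried, 14 crossed 2-fold and 1 reversed; of 232 list positions, 4 fell inside the random range, 12 moved outside it (the Notch list in the CD133 sort under 2 settings among them) and 0 reversed. Signal near the floor limits what the values of dim genes can show.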

Other observations

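The intestinal list was chosen after the opposite pattern was seen, and its values after the list was written; every value in this part was picked after the report's results were known.

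Beyond the named genes, the genes of opposite direction included others not named so far. The trefoil factor TFF1 differed by 1.59 in the CD133 sort and -1.24 in the ALDH sort, the ferroxidase HEPH by 1.95 and -1.33, the annexins ANXA1 by 1.89 and -1.57 and ANXA13 by 1.35 and -1.48, and the enzyme UGT8 by 1.36 and -1.24. HEPH lay below the floor in CD133-negative and ALDH-positive cells. Set against the floor it differed by 0.03 and -0.47, short of 2-fold in both sorts. The trypsinogen PRSS3 (1.05 and -1.15) can share signal with its pseudogene. Of the 47 genes, 41 had their lowest value in CD133-negative and their next lowest in ALDH-positive cells. The way these genes were chosen lets only CD133-negative or ALDH-positive cells be lowest, so this order was partly fixed in advance. Among the 47, 37 were higher in ALDH-negative than in CD133-positive cells, with a median of 0.46 over all 47. PROM1 ran the other way between those fractions, at -0.61.

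The intestinal list held 27 genes, of which 25 were measured and 13 lay above the floor in CD133-negative cells. In the CD133 sort 23 of the 25 were higher, with a median of 0.30 above all random lists, and in the ALDH sort 18 were lower, with a median of -0.27 at percentile 0.01. The tetraspanin TSPAN8 (1.29 and -1.12) and the guanylate cyclase receptor GUCY2C (1.15 and -1.18) were at least 2-fold different in both sorts, and the metalloprotease MEP1A (0.70 and -1.36) in the ALDH sort. The intestinal transcription factor CDX2 had log2 levels of 8.53 in CD133-positive, 7.63 in CD133-negative, 7.90 in ALDH-positive and 8.58 in ALDH-negative cells, so it was well above the floor on all 4 arrays. The actin bundler VIL1 differed by 0.30 and -0.53.

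SLC51A, SLC7A11 and VIM were at least 2-fold different in 1 sort and near 0 in the other, a contrast that was not tested. SLC51A differed by 0.03 in the CD133 sort and -1.83 in the ALDH sort, and SLC7A11 by -0.10 and -1.23, while VIM differed by 1.03 and -0.03. Histone genes in ALDH-negative cells had a median of -0.52 against the mean of the CD133 arrays, with 9 of 10 lower, and those in ALDH-positive cells -0.18, inside the random range. That comparison crosses the sorts, so it does not place the difference in either ALDH fraction.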
